A study of Mus musculus with 6 samples.

How the data were processed

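Single-cell RNA was measured in 4 gene expression libraries, 1 library per group, from 6-week-old female C57BL/6 mice. The groups were mock-treated wild type (WT), mock-treated CCR2 knockout (KO), WT infected with murid herpesvirus 4 (MuHV-4, a mouse gammaherpesvirus) and CCR2 KO infected with MuHV-4. Per the labels, lungs were perfused and digested with collagenase D and DNase I, and monocytes and CD4 T cells were sorted by flow cytometry. Cell numbers were made equal and 16000 cells were loaded on the 10x Chromium 3′ v3 system. The mock libraries held lung cells. In the infected libraries, lung cells and bronchoalveolar lavage cells were marked with barcoded antibodies (hashtags) and pooled, and 2 further libraries held the hashtag counts. The labels did not say which hashtag marked which tissue, how many mice were pooled, the virus dose or the day of infection. The tags are therefore called HTO_5 and HTO_6, and no tissue was inferred from expression.

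The deposited gene expression matrices held UMI counts (unique molecular identifiers, whole numbers of molecules per gene and barcode). Cell Ranger 3.0.2 wrote them, per the file headers and the submitters' processing notes, and the genome build named in those notes was GRCm38 (mm10). The deposited hashtag matrices held counts per tag and barcode, and the tool that made them is not given in the sources used here. The gene expression matrices listed 22597 features, of which 22503 IDs were found in the GENCODE vM21 annotation of GRCm38 and 22403 carried the same symbol there. Gene symbols were taken as the files pair them with IDs. Genes with near-identical copies, such as Hspa1a and Hspa1b, H2-Q6 and H2-Q7, or members of the Ly6 and Ifit families, can share reads, and their split is uncertain.

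Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. These limits removed 246 barcodes from mock WT, 404 from mock KO, 732 from infected WT and 468 from infected KO. A barcode with at least 10 hashtag counts, of which at least 80% came from 1 tag, was assigned to that tag. Barcodes mixed for both tags were removed as doublets, which took out 701 cells of infected WT and 516 of infected KO. At a purity of 65% only 134 and 205 were mixed, so not every removed barcode need be a doublet. In infected WT, HTO_5 barcodes numbered 1653 at 80% and 2158 at 65%, and HTO_6 barcodes 1626 and 1688. Scrublet was run per library at its automatic threshold and marked 25 cells, 0.228% of those examined, which is too few for a working doublet call. The marked cells were removed. Other doublets within a tag, and other doublets of the mock libraries, therefore stayed in the data. After these steps 9749 cells with 79696931 UMIs remained.

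All kept cells were clustered together with scanpy 1.11.5. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen without T cell receptor, immunoglobulin variable, mitochondrial and ribosomal genes, and 30 principal components with 15 neighbours were passed to Leiden clustering (leidenalg 0.10.2) at resolution 1. No batch correction was applied, since library and group were the same. A cluster was named only when its 50 leading genes held at least 3 markers of 1 of 23 marker sets and its 10 leading genes did not hold more markers of the other sets together than of its own. Ccr2, the deleted gene, was left out of the marker sets. Of the 23 clusters, 3 stayed unnamed. The T cell class joined the clusters named T cell. The monocyte/macrophage class joined the clusters named classical monocyte-like, nonclassical monocyte-like, and monocyte-derived or interstitial macrophage-like.

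Levels are CPM, the UMI counts of a gene scaled to 1000000 UMIs of the class in a library, from UMIs summed over cells. Genes at 20 or more CPM in either library of a comparison were measured. The 95% intervals are exact Poisson for levels, exact Clopper-Pearson for shares, and conditional exact binomial for ratios of levels. They cover counting error only. A fold against a level of 0 was computed against 3 counts and is given as a lower bound. For counts of genes and for list medians, 10 CPM was added to both levels before the log2 ratio, which pulls low genes towards 0, and a gene counted as higher or lower at 2-fold. Folds of single genes are plain ratios. With 1 library per group no test, standard error or p-value was computed, and differences describe libraries.

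The comparisons were infection in WT, infection in CCR2 KO, genotype under infection and genotype in mock, each within both classes, and HTO_6 against HTO_5 within each infected library. Named genes followed a rule. From each comparison and class it took the 6 genes with the largest log2 ratio upwards and the 6 downwards among genes at 100 or more CPM and in at least 10% of the class cells of the higher library, at least 2-fold apart. Mitochondrial, ribosomal, haemoglobin, T cell receptor and immunoglobulin genes, unnamed gene models, and genes at over 10 times the level in another class of 50 or more cells of the same library were left out. The last filter, aimed at free RNA, left out 2 genes among those higher in each class under infection in WT, 7 in each class under infection in KO, 2 monocyte/macrophage genes higher in infected KO than in infected WT, and 5 genes lower in HTO_6 monocytes and macrophages of infected KO. Ccr2, the genes of the share results, and the 2 to 4 members of each list with the largest absolute log2 ratio at 100 or more CPM were added.

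In total 24 gene lists were used, 14 in T cells and 15 in monocytes and macrophages, with 5 of them in both. The T cell lists were Th1 programme, cytotoxic granule and effector, regulatory T cell, T follicular helper, naive and recirculating T cell, tissue-resident T cell, inhibitory receptor, Th2 and Th17. The monocyte/macrophage lists were MHC class II, IFN-gamma-induced effector, T cell co-signalling ligand, chemokine, inflammatory and regulatory cytokine, alternative activation, macrophage differentiation, lipid handling, classical monocyte and nonclassical monocyte. Both classes used the lists type I interferon-stimulated, MHC class I presentation, cell cycle, glycolysis, and dissociation and immediate early response. Of all list members, 1 gene (Mx1) was missing from the matrices. The median log2 ratio of each list was ranked among 10000 random lists of the same size matched on mean level in 20 bins. This percentile describes these libraries and is no test. Intervals of list medians came from 200 Poisson draws.

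Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs, with shallower cells left out, and are given beside the share in the other class as background. In the infected libraries this background includes cells with transcripts of both lineages, so it is no measure of free RNA alone. The groups, classes, markers, lists, comparisons, thresholds and the rule for named genes were fixed before the data were examined. Alternatives fixed at the same time were 200 or 1000 genes per cell, a mitochondrial limit of 5%, no doublet removal, clustering resolution 0.5 or 1.5, hashtag purity of 65% or 90%, a hashtag minimum of 50 counts, each hashtag alone, TMM scaling, the mean over cells in place of the sum, a minimum level of 50 CPM or none, 1 CPM added in place of 10, and thinning to 1000 UMIs or none. Alternatives added after the data were seen left out cells with at least 3 T lineage and 5 myeloid UMIs, joined the T-dominant cells of the cycling cluster to the T cell class, and compared parts of the monocyte/macrophage class. The TMM factors were computed in Python and checked against edgeR 4.0.16 in R 4.3.3.

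The comparison code was tested on simulated data drawn from the real levels and depths, with 200 genes changed, 50 per fold size. The simulated sums held Poisson counting error only, with no variation between cells, mice or libraries. They therefore give no rate of false calls for comparisons of single libraries. No unchanged gene was called in any of the 8 simulated comparisons. Of genes changed 3-fold, between 92% (genotype in mock, both classes) and 100% (infection in WT, monocytes and macrophages) were called, and of genes changed 5-fold 100% in every comparison. Of genes changed exactly 2-fold, from 4% to 16% were called, since adding 10 CPM lowers their ratio, and no gene changed 1.5-fold was called. The 95% intervals held the true ratio for 94.9% (genotype under infection, T cells) to 96.0% (infection in WT, monocytes and macrophages) of genes.

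Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Cells outside the T cell and monocyte/macrophage classes were not compared gene by gene between groups, but entered the shares, the filter against other classes, reference levels of cytotoxic genes and, for the cycling cells, 1 alternative. Hashtag counts that matched neither tag were not used in the comparisons. The smallest class sum, 2551689 UMIs in monocytes and macrophages of mock KO, made 1 UMI worth 0.392 CPM.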

Results

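Lung monocytes and CD4 T cells of WT and CCR2 KO mice were profiled by droplet single-cell RNA sequencing after mock treatment or infection with MuHV-4. CCR2 is the chemokine receptor that lets classical monocytes leave the bone marrow, and the comparisons ask how infected and mock cells of both kinds differ and how CCR2 KO cells differ from WT cells. Each of the 4 groups was 1 library, so no difference has a replicate check and every interval is counting error only. Mock WT held 1992 barcodes with 14323510 UMIs, mock KO 2632 with 12957141, infected WT 4726 with 40600991 and infected KO 3489 with 29342664. After filtering, the 4 libraries kept 1731, 2225, 3289 and 2504 cells with median depths of 5940, 4560, 6836 and 6611.5 UMIs. The infected libraries pooled lung with bronchoalveolar lavage cells and the mock libraries held lung cells, so infection and the added compartment cannot be separated in any infection comparison.

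Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557, GRCm38) was lower in both KO libraries. In monocytes and macrophages it stood at 698 CPM in mock WT and 30.2 in mock KO, 23.1-fold lower (interval 18.5 to 29.4). In the infected libraries it stood at 425 CPM in WT and 87.2 in KO, 4.87-fold lower (4.45 to 5.34). The class held different mixes, with 632 of 892 classical monocyte-like cells in mock WT and 96 of 344 in mock KO. Within classical monocyte-like cells Ccr2 stood at 823 CPM in mock WT and 69.6 in mock KO. In the infected libraries it stood there at 595 CPM in WT and 119 in KO. In T cells it stood at 41.7 CPM in mock WT, 7.53 in mock KO, 465 in infected WT and 128 in infected KO. Transcripts of the deleted gene remained in the KO libraries, and the labels do not say which part of the gene was deleted, so a 3′ tag outside that part would not check the labels. In infected KO, 12.7% of thinned monocytes and macrophages held a Ccr2 UMI against 19.8% of T cells. Ccr2 stood higher in T cells than in monocytes and macrophages of both infected libraries, so the T cell share is no background for it. No expression specific to the monocytes was read from these shares.

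Classical monocyte-like cells made up 36.5% of kept cells in mock WT (34.2 to 38.8) and 4.31% in mock KO (3.51 to 5.24), and 14.6% in infected WT (13.4 to 15.8) and 5.99% in infected KO (5.09 to 6.99). Nonclassical monocyte-like cells, the patrolling blood monocytes, made up 225 of 1731 cells in mock WT, 10.1% in mock KO, 3.25% in infected WT and 7.83% in infected KO. Monocyte-derived or interstitial macrophage-like cells made up 2.02% and 1.03% in the mock libraries, 15.6% in infected WT and 8.39% in infected KO. T cells made up 41.2% in mock WT, 75.2% in mock KO, 54.0% in infected WT and 51.1% in infected KO. Cells were sorted and their numbers equalised before loading, so these shares describe the loaded mixtures. With a mitochondrial limit of 5% the T cell share fell to 13.4% in mock WT and 39.0% in mock KO.

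**Figure D1:**
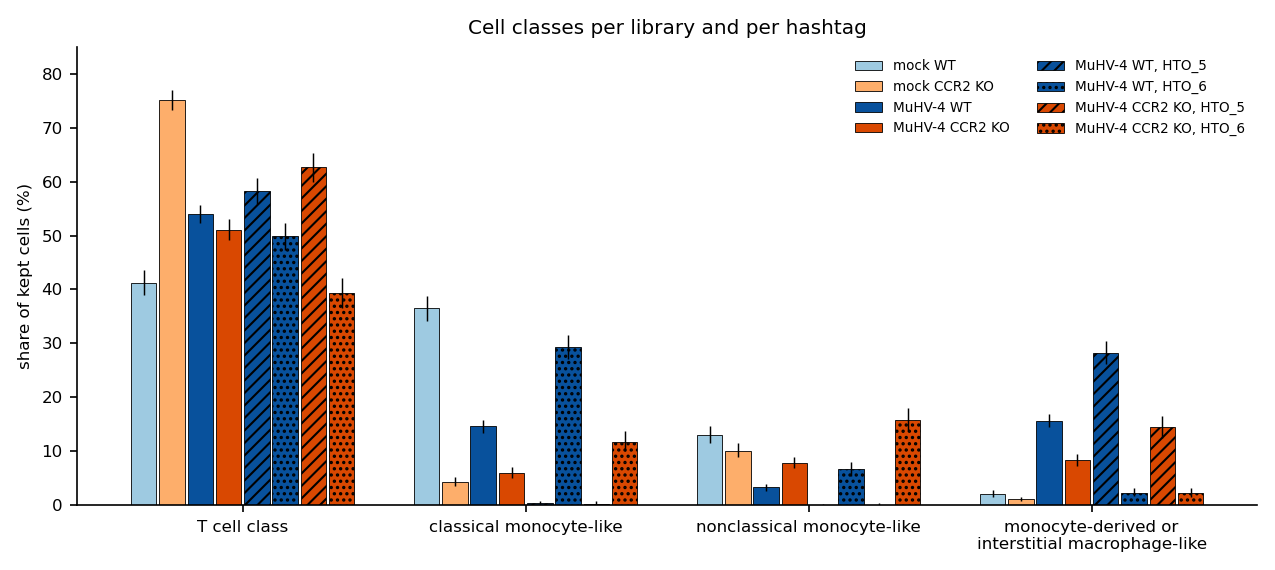
Bars show the percent of kept cells in the T cell class and in the 3 parts of the monocyte/macrophage class, for the 4 libraries and for each hashtag of the infected libraries, with exact 95% intervals. Classical monocyte-like cells stood at 36.5% in mock WT and 4.31% in mock KO.

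Different clusters held the classes in the mock and infected libraries. Clusters 0 and 2 held most T cells of mock WT (450 and 159 of 714) and of mock KO (1003 and 461 of 1673). Clusters 1, 5 and 8 held most T cells of infected WT (585, 382 and 361 of 1775) and of infected KO (488, 336 and 245 of 1280). Most classical monocyte-like cells lay in cluster 4 in the mock libraries (591 of 632 in WT) and in cluster 7 in the infected ones (434 of 480 in WT), and most macrophage-like cells of the infected libraries lay in cluster 6. The genes that define these clusters differ between mock and infected libraries, so cluster sizes were not compared as populations. The 3 unnamed clusters stayed out of both classes. Cluster 9, led by cell cycle genes such as Birc5 and Stmn1, held 1.10%, 2.61%, 6.93% and 8.43% of mock WT, mock KO, infected WT and infected KO cells. Cluster 12, led by Prf1, Gzma, Cd8b1 and Cd8a, held no cell of the mock libraries, 1.49% of infected WT and 5.99% (5.09 to 6.99) of infected KO. Cluster 21, with leading genes of cytotoxic cells and nonclassical monocytes, held 0.182% of infected WT and 0.839% of infected KO.

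Infection in WT separated T cells mainly by effector and interferon-induced genes, which were higher, and by naive T cell genes, which were lower. Plac8 stood at 3283 CPM in infected WT and 35.2 in mock WT, 93.3-fold higher (77.6 to 113). The granzyme gene Gzmb stood at 980 against 21.3 CPM, 46.0-fold higher (36.3 to 59.2), and the inhibitory receptor gene Lag3 at 496 against 1.85 CPM, 268-fold higher (123 to 730). The chemokine gene Ccl4 was 169-fold higher (99.0 to 318), and Ifitm1 and Ifitm3, which encode antiviral membrane proteins, were 73.8-fold (47.7 to 121) and 34.9-fold (28.9 to 42.6) higher. The lymph node homing receptor gene Ccr7 fell from 552 to 45.8 CPM, 12.1-fold lower (10.9 to 13.4). Igfbp4, Tubb2a, Dapl1, Dusp10 and the interferon-gamma receptor gene Ifngr2 were 11.8-fold, 14.0-fold, 13.6-fold, 7.90-fold and 10.7-fold lower. Of 5416 measured genes 729 were at least 2-fold higher and 163 lower, and the median gene stood 0.31 higher on the log2 scale. The difference between this scaling and TMM exceeded 0.1, so list medians of both infection comparisons are given relative to the median gene, as are those of the mock genotype comparison in monocytes and macrophages and of the hashtags.

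Relative to the median gene, the type I interferon-stimulated list stood 2.51 higher in infected WT T cells, with 23 of 23 members at least 2-fold higher, among them Ifi204 (210 against 1.24 CPM), Ly6a (2814 against 145) and Isg20 (334 against 10.2). The Th1 programme stood 1.73 higher with 13 of 15 members higher, among them Ccl5 (7592 against 538 CPM), Ccl3 (190 against 1.24) and Id2 (1262 against 138). The cytotoxic list stood 1.23 higher with 8 of 12 members higher, including Nkg7 (1452 against 111 CPM) and Gzmk (109 against 6.79). Inhibitory receptors stood 2.21 higher with 5 of 7 members higher, including Pdcd1 (322 against 17.6 CPM) and Ctla4 (652 against 130), while Nr4a2 was 3.16-fold lower. The tissue-resident list stood 1.24 higher with 6 of 9 members higher, led by Cxcr6 (756 against 83.7 CPM) and Rgs1 (922 against 128). The regulatory T cell and T follicular helper lists stood 0.89 and 1.13 higher, with members such as Tnfrsf4 (664 against 102 CPM), Maf (6.06-fold) and Icos (3.08-fold). The naive and recirculating list stood at -2.21 with 13 of 14 members lower, including Lef1 (5.10-fold lower). All of these medians lay above the 99th percentile of random lists, or below every random list for the naive genes. MHC class I presentation stood 0.82 higher (Tap1 4.14-fold) and glycolysis 0.37 higher (Gapdh 2.21-fold). Cell cycle stood at -0.11 in a class that left out the cycling cluster 9, and its raw median of 0.19 was 1.15 with the T cells of that cluster joined, 0.75 at a minimum of 200 genes per cell, and below 0 under TMM, at the mitochondrial limit of 5% and at a minimum level of 50 CPM. Th17 stood at -0.70 over 4 measured members, with a raw median that changed sign when cells were weighted equally. Th2 stood at -0.42 over 2 members, but its raw median turned from -0.11 to 0.62 at clustering resolution 1.5 and to 0.57 at a minimum level of 50 CPM, so no direction was read. The dissociation list stood at -0.60, with Hspa1a 3.74-fold higher and Fosb 3.18-fold lower, and its raw median turned from -0.29 to 0.22 with HTO_6 cells alone.

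Shares of thinned T cells with a UMI moved the same way. Gzmb was found in 0.990% of mock WT and 41.6% (39.3 to 44.0) of infected WT T cells, against 0 of 863 and 9.74% of monocytes and macrophages as background. In infected WT Cxcr6 was found in 56.7% (mock WT 7.92%, background 6.05%), Pdcd1 in 32.0% (2.55%, background 2.55%), Ifng in 19.8% (2.40%, background 3.31%), Gzmk in 13.7% (0.566%, background 2.46%) and Icos in 78.4% (38.8%, background 8.42%). In mock WT monocytes and macrophages Cxcr6, Ifng and Gzmk were found in 0 of 863 cells, and Pdcd1 and Icos in 0.116%. In infected WT, cells of both lineages held 8572 of the 8689 Gzmb UMIs of monocytes and macrophages. They also held 1165 of the 1187 Cxcr6 UMIs. The background shares of Gzmb and Cxcr6 are therefore no measure of free RNA. Il10 was found in 0.283% and 5.78% (background 1.42%), and the regulatory T cell gene Foxp3 in 1.84% and 2.92% (background 0.116% and 0.0946%). The mock WT share of Il10 was close to its background of 0.232%. Gzma was found in 8.63% of infected WT T cells and 6.34% of monocytes and macrophages, and Bcl6 in 2.51% and 9.46%. Gzma stood at 133 CPM in these T cells and at 5.62 in monocytes and macrophages with no T lineage UMI. The 6.34% is therefore no measure of free RNA. The T cell shares were still not read as expression, since cell pairs were not separated and the source of Bcl6 in monocytes and macrophages was not tested. Mki67 at 2.86% (background 2.55%) was not read, since cluster 9, with Mki67 among its 10 leading genes, was outside the class. Cxcr5 was found in 0.467% of infected WT T cells and in 0 of 1057 monocytes and macrophages. Cd8a was found in 0.408% of infected WT T cells, below its background of 2.46%, and in 0 of 707 mock WT T cells. Median depths were 4383 and 5171 UMIs in T cells and 8736 and 10500 in monocytes and macrophages, and 7 and 61 T cells were too shallow. Without thinning, Gzmb was found in 1.68% and 52.5%, Cxcr6 in 10.6% and 70.1%, and Ifng in 3.64% and 33.8% of T cells.

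In WT monocytes and macrophages infection went with higher chemokine, interferon-induced and macrophage genes and with lower genes of resting monocytes. Macrophage-like cells made up 35 of 892 cells of this class in mock WT and 514 of 1101 in infected WT. The class values therefore hold different mixes of cells. Spp1, which encodes osteopontin, stood at 1073 CPM in infected WT and 7.48 in mock WT, 143-fold higher (113 to 184). Ccl8, a monocyte chemokine gene, stood at 499 against 0.325 CPM (3 UMIs), a ratio of 1533 (524 to 7434), and Cxcl9, which encodes a chemokine for activated T cells, at 504 against 1.84 CPM, 274-fold higher (171 to 470). AA467197 was 260-fold higher and Arg1 273-fold higher. Nos2 was at least 105-fold higher. Lyz1, Trf, the neutrophil chemokine gene Cxcl2, the prostaglandin-degrading gene Hpgd, and the matrix genes Fn1 and Thbs1 were 9.37-fold, 6.47-fold, 5.02-fold, 5.20-fold, 4.48-fold and 3.96-fold lower. Of 5786 genes 510 were at least 2-fold higher and 136 lower.

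The chemokine list stood 3.14 higher with 9 of 14 members higher and 3 lower, and Ccl12 rose from 4.01 to 638 CPM. The IFN-gamma-induced effector list stood 2.24 higher with 18 of 19 members higher, including Iigp1 (284-fold), Gbp4 (70.7-fold) and Socs1 (32.1-fold). Macrophage differentiation stood 2.68 higher with 15 of 19 members higher, including Gpnmb (102-fold), Cd63 (20.6-fold) and C1qa (11.9-fold). Type I interferon-stimulated genes stood 1.70 higher with 22 of 25 higher, such as Ly6a (55.3-fold) and Ifit1 (12.4-fold). MHC class I presentation stood 1.22 higher (H2-Q7 6.79-fold) and MHC class II 0.81 higher, with H2-Ab1 at 3605 against 1701 CPM and H2-Aa at 2991 against 1597, 1.87-fold (1.84 to 1.91). The co-signalling list stood 0.23 higher with 4 of 9 members higher, among them Cd274 (PD-L1, 8.45-fold) and Cd40 (3.58-fold). The cytokine list stood at -0.15, with Il18bp 112-fold higher and Il1b 1.92-fold lower, and its raw median changed sign when cells were weighted equally. Alternative activation stood at -0.44 with 4 members higher and 4 lower, and Retnla fell from 185 to 0.585 CPM. Its raw median turned from -0.35 to 0.42 with HTO_5 cells alone and to 1.17 with the mitochondrial limit of 5%. The classical monocyte list stood at -0.86 and the nonclassical list at -0.96, with Cx3cr1 3.60-fold lower. Within classical and nonclassical monocyte-like cells the raw medians were -0.34 and 0.03 for the classical list and 0.009 and -0.20 for the nonclassical list. Macrophage differentiation stood at 1.31 and -0.50 there, chemokines at 2.51 and 1.20, and IFN-gamma-induced effectors at 2.39 and 2.16. Lipid handling stood at 0.03 with Fabp5 18.8-fold higher and a raw median that changed sign under TMM, glycolysis 0.40 higher, and the dissociation list at -0.56. Cell cycle stood 1.28 higher with Tuba1b 2.86-fold and Tubb5 2.56-fold higher, but its raw median fell from 1.37 to 0.092 without the cells of both lineages and to 0.42 with cells weighted equally. With HTO_6 cells alone the raw medians were 0.23 for cell cycle, 1.23 for macrophage differentiation in place of 2.77, and -0.27 and -0.35 for the classical and nonclassical lists in place of -0.77 and -0.87.

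H2-Aa was found in 35.8% (32.6 to 39.1) of thinned mock WT and 72.8% (70.0 to 75.4) of infected WT monocytes and macrophages, against 2.55% and 6.07% of T cells. In infected WT Cxcl9 was found in 24.4% (mock WT 0.348%, T cell background 12 of 1714), C1qa in 40.9% (4.29%, background 1.81%), Cd274 in 36.5% (7.18%, background 9.10%) and Spp1 in 26.1% (1.16%, background 1.93%). Arg1 was found in 11.3% (0.116%, background 0.350%), Il1b in 54.6% (81.5%, background 2.16%), Treml4 in 13.6% (23.2%, background 0.0583%), Ly6c2 in 71.5% (50.1%, background 20.8%) and Nos2 in 4.16% (0 of 863, background 0.117%). In mock WT T cells the background was 0 of 707 for Cxcl9, C1qa, Spp1, Arg1 and Nos2, 2.97% for Cd274, 2.40% for Il1b, 0.141% for Treml4 and 1.56% for Ly6c2. The Ccr2 share of 46.4% in infected WT stood close to the 42.9% of T cells, which is no background for this gene. Unthinned shares of H2-Aa were 42.8% and 80.7%, and of Cxcl9 0.785% and 40.1%, and 29 and 44 cells were too shallow.

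Genes of cytotoxic lymphocytes appeared in the same class. Gzma stood at 808 CPM in infected WT against 0.217 (2 UMIs), a ratio of 3724 (1031 to 30757), Gzmb at 508 CPM was at least 1563-fold higher, and Ccl5 stood at 2028 against 27.5 CPM. Cells with transcripts of both lineages made up 1.46% of the class in mock WT, 2.91% in mock KO, 19.0% in infected WT and 21.4% in infected KO. These cells were deep and held 6.55e+06 of 1.71e+07 class UMIs in infected WT and 2.65e+06 of 5.77e+06 in infected KO. They therefore weigh more in the summed levels than in the cell shares. Without these cells Gzma stood at 35.1, Gzmb at 11.1 and Ccl5 at 894 CPM in infected WT. Median mitochondrial shares in monocytes and macrophages were 3.59%, 3.46% and 2.82% in mock WT, mock KO and infected WT and lowest in infected KO, and in T cells of the 4 libraries 6.00%, 6.31%, 3.96% and 4.01%.

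**Figure D2:**
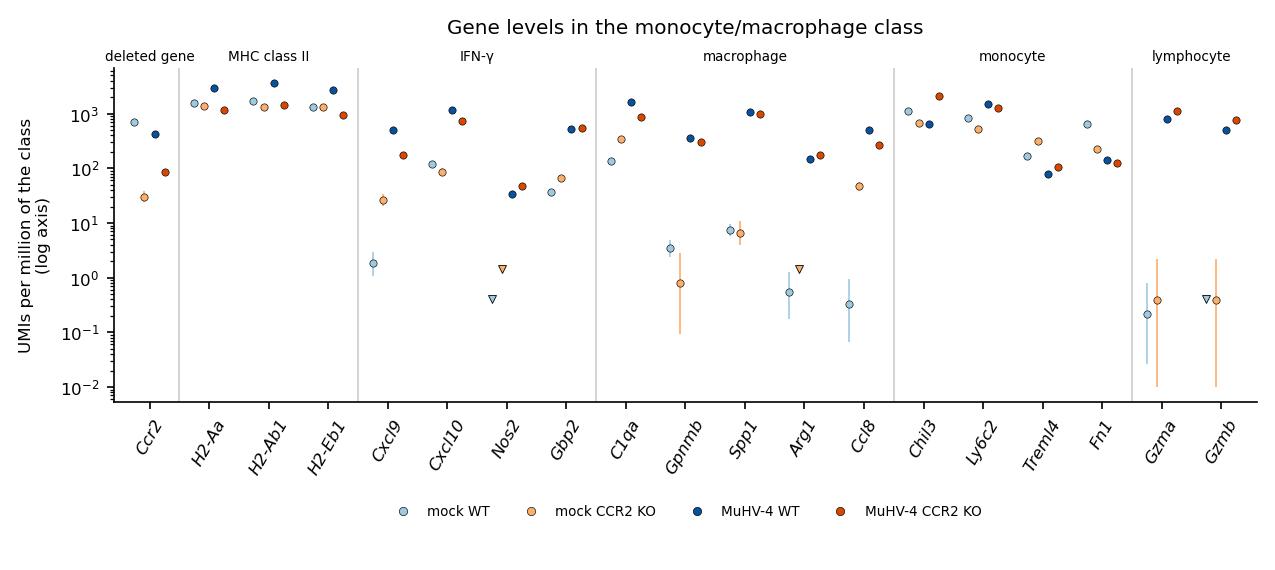
Points show CPM of named genes in monocytes and macrophages of the 4 libraries on a log axis, with exact Poisson 95% intervals. Triangles mark 0 counts at the upper bound of that interval. Spp1 stood at 1073 CPM in infected WT and 7.48 in mock WT, and Ccr2 was lower in both KO libraries.

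Infection in CCR2 KO gave T cells much of the same picture. Ifitm1 stood at 1340 CPM in infected KO against 0.529 (4 UMIs) in mock KO, 2534-fold higher (989 to 9302), and Ifitm3 at 1561 against 8.85 CPM, 176-fold higher (139 to 228). Plac8 was 86.8-fold, Ifitm2 93.6-fold, Lag3 157-fold and Gzmb 37.1-fold higher. Ccr7 fell from 606 to 26.3 CPM, 20.1-fold to 26.5-fold lower by its interval, Igfbp4 was 11.1-fold to 15.3-fold lower, and Ifngr2, Tubb2a, Dusp10 and the T cell receptor adaptor gene Trat1 were 19.8-fold, 14.3-fold, 10.1-fold and 11.9-fold lower. Of 5500 genes 766 were at least 2-fold higher and 189 lower. Relative to the median gene, type I interferon-stimulated genes stood 2.25 higher with 23 of 23 members higher, the Th1 programme 1.57 higher with Cxcr6 14.6-fold and Ifng 25.4-fold higher, inhibitory receptors 1.98, cytotoxic genes 1.53 with Gzmk 27.4-fold higher, the tissue-resident list 1.26, T follicular helper 1.09, MHC class I 0.85 and regulatory T cell genes 0.82 higher. The naive list stood at -2.24 with 13 of 14 members lower. Th2 stood at -1.28 over 3 members, but its raw median turned from -0.98 to 0.14 at a minimum level of 50 CPM and was -0.29 at resolution 1.5, so no direction was read. Th17 stood at -0.76 over 2, cell cycle at -0.03 without cluster 9 (its raw median of 0.28 was 0.85 with the T cells of that cluster joined and below 0 under TMM and at a minimum level of 50 CPM), glycolysis at 0.38 and dissociation at -0.63, whose raw median turned from -0.33 to 0.29 with HTO_6 cells alone. With the mitochondrial limit of 5% the raw medians were 0.068 for regulatory T cell genes in place of 1.13, 0.82 for cytotoxic genes in place of 1.83 and 0.76 for the tissue-resident list in place of 1.56. Gzmb was found in 1.46% of mock KO and 50.5% (47.7 to 53.3) of infected KO T cells (background 0 of 335 and 11.2%), Cxcr6 in 6.14% and 64.6% (0 of 335 and 11.8%), Ifng in 1.28% and 23.3% (0 of 335 and 3.85%), and Pdcd1 in 2.98% and 36.5% (0 of 335 and 5.39%). In infected KO monocytes and macrophages, cells of both lineages held 4488 of 4511 Gzmb UMIs and 1041 of 1045 Cxcr6 UMIs, so these background shares are no measure of free RNA. Unthinned Gzmb shares were 2.03% and 62.4%, and 28 and 52 T cells were too shallow at median depths of 4342 and 5816 UMIs.

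In KO monocytes and macrophages the interferon and chemokine genes were also higher in the infected library. Spp1 was 145-fold (90.5 to 249) and Ccl5 103-fold (78.6 to 139) higher. Of the 11932 Ccl5 UMIs of the class in infected KO, 10552 lay in the cells of both lineages. Ccl5 stood at 2068 CPM in the class and at 467 CPM in its cells with no T lineage UMI. Gzma, Gzmb and Nkg7, which the cells of both lineages carried, stood at 1125, 782 and 473 CPM with all cells and at 14.4, 7.37 and 6.73 without those cells. Hpgd, the activation gene Cd83, Tmem176b, Mef2c, the fractalkine receptor gene Cx3cr1 and Trf were 7.01-fold, 4.93-fold, 5.17-fold, 5.04-fold, 4.80-fold and 5.04-fold lower. Of 6018 genes 581 were at least 2-fold higher and 216 lower. IFN-gamma-induced effectors stood 2.44 higher with 18 of 19 higher (Gbp4 46.7-fold), type I interferon-stimulated genes 2.42 higher with 25 of 25 higher (Ifit1 45.6-fold), chemokines 2.27 higher (Ccl7 27.8-fold, Ccl2 11.7-fold), macrophage differentiation 1.29 higher (Cd63 9.34-fold), MHC class I 1.17, co-signalling 0.69 (Cd274 5.46-fold) and cytokines 0.44 higher. Alternative activation stood 0.87 higher, with Chil3, which encodes a chitinase-like protein, 3.18-fold (3.03 to 3.35) and Arg1 at least 150-fold higher. Its raw median turned from 0.92 to -0.36 with HTO_6 cells alone and was 0.23 without the cells of both lineages. MHC class II stood at -0.25, with H2-Aa 1.14-fold (1.10 to 1.19) lower, and its raw median turned from -0.19 to 0.23 with the mitochondrial limit of 5%. The nonclassical list stood at -1.42 with 16 of 24 members lower, the classical list at -0.12, lipid handling at -0.28, glycolysis at 0.30, dissociation at -0.49 and cell cycle at 1.06. Macrophage-like cells made up 23 of 344 cells of the class in mock KO and 210 of 556 in infected KO. Within classical and nonclassical monocyte-like cells the raw medians were -0.47 and -0.11 for the nonclassical list and 0.32 and 0.93 for the classical list. Macrophage differentiation stood at 1.13 and -0.18 there, chemokines at 1.97 and 1.49, and IFN-gamma-induced effectors at 2.05 and 1.90. With HTO_6 cells alone the raw medians were 0.44 for macrophage differentiation in place of 1.34, and -0.69 and 0.57 for the nonclassical and classical lists in place of -1.37 and -0.067. The raw co-signalling median fell from 0.75 to 0.28 without the cells of both lineages and to 0.26 under TMM. The raw cell cycle median fell from 1.12 to -0.039 without the cells of both lineages, and the raw classical monocyte median changed sign when cells were weighted equally.

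The infection comparisons of WT and KO used different libraries. In T cells 618 genes were at least 2-fold higher in both, where lists of 721 and 747 of 5293 genes drawn independently would share 102, and 137 were lower in both (5.35 by independence). In monocytes and macrophages 431 genes were higher (46.2) and 90 lower (4.66) in both, and in neither class was any gene 2-fold apart in opposite directions. Differences between the genotypes' infection effects were not tested. The KO effect minus the WT effect was -1.09 for the MHC class II median, 2.44 for Chil3, -3.11 for Cxcl9 and -3.32 for Ccl8 in monocytes and macrophages. In T cells it was 2.15 for Ifitm1, -0.11 for Plac8 and -0.16 for Gzmb on the log2 scale. The effects of Cxcl9 and Ccl8 in monocytes and macrophages were 5.44 and 5.62 in WT and 2.33 and 2.30 in KO. Both genes differed less than this between infected KO and infected WT. Part of each difference therefore comes from higher levels in mock KO than in mock WT, where the class held 344 and 892 cells.

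Under infection, KO and WT T cells were close to each other. Of 5289 measured genes 3 were at least 2-fold higher in KO and 7 lower. Ifitm1 stood at 1340 CPM in KO and 456 in WT, 2.94-fold higher (2.84 to 3.04), and Gzma at 311 against 133, 2.34-fold higher (2.19 to 2.49). Gzma was found in 8.63% of thinned T cells in WT and 12.9% in KO, and in 6.34% and 8.48% of monocytes and macrophages. Monocytes and macrophages with no T lineage UMI held only 5.62 and 14.3 CPM of Gzma, so their class shares are no measure of free RNA. The Gzma difference was still not read as expression by T cells of this class, since pairs of T cells with cytotoxic cells were not separated. Cluster 12, at 13755 and 17930 CPM of Gzma, held 49 cells of infected WT and 150 of infected KO. Ccr2 was 3.62-fold lower (3.38 to 3.87), and the heat shock genes Hspa1b and Hspa1a were 3.36-fold (3.12 to 3.62) and 2.86-fold (2.64 to 3.09) lower. The third higher gene, chosen after its values were seen, was the unnamed model 2010315B03Rik at 35.4 against 8.05 CPM. The Th1 programme stood 0.17 higher and the cytotoxic list 0.25 higher, with Cxcr6 1.28-fold, Ifng 1.21-fold and Gzmb 1.18-fold (1.15 to 1.21) higher, while the type I interferon-stimulated list stood at -0.22, with Isg15 1.43-fold and Ifi27l2a 1.28-fold lower. MHC class I stood at -0.12, tissue-resident genes at 0.15 with Cd69 1.38-fold higher, and glycolysis at 0.12. Th17 stood at -0.97 over 3 members. The other 7 T cell lists had medians from -0.08 to 0.04, and those of T follicular helper and dissociation genes changed sign under TMM and those of regulatory T cell genes and inhibitory receptors with cells weighted equally. Pdcd1 (1.05-fold, 1.00 to 1.11) and Icos (interval 0.982 to 1.04) were not distinguishable at this depth. Thinned shares in infected WT and KO were 41.6% and 50.5% for Gzmb (background 9.74% and 11.2%), 56.7% and 64.6% for Cxcr6 (6.05% and 11.8%), 19.8% and 23.3% for Ifng (3.31% and 3.85%), and 5.78% and 9.28% for Il10 (1.42% and 1.93%). The T cell class held different mixes. Clusters 0 and 2, which held most mock T cells, held 126 and 207 of 1775 T cells in infected WT. In infected KO they held 64 and 93 of 1280. HTO_5 cells numbered 963 and 783 in the class. The effect of these mixes on the shares and list medians was not tested.

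In monocytes and macrophages of the infected libraries, KO cells had lower MHC class II genes. H2-Eb1 stood at 960 CPM in KO and 2688 in WT, 2.80-fold lower (2.72 to 2.88), H2-Aa (chromosome 17, 34282744 to 34287823) at 1186 against 2991, 2.52-fold lower (2.46 to 2.59), H2-Ab1 at 1451 against 3605 and H2-DMb1 at 151 against 371. The MHC class II median stood at -1.24 with 6 of 7 members at least 2-fold lower, below every random list. H2-Aa was found in 40.8% (36.6 to 45.2) of thinned KO cells and 72.8% of WT cells, against 1.14% and 6.07% of T cells, and unthinned in 51.3% and 80.7%. Cxcl9 stood at 172 against 504 CPM, 2.93-fold lower (2.74 to 3.13), and was found in 9.06% (6.73 to 11.9) against 24.4% of cells (background 0.407% in KO and 12 of 1714 in WT). Cxcl10, Ccl8, C1qb and C1qa were 1.57-fold, 1.84-fold, 2.03-fold and 1.84-fold lower, and C1qa was found in 21.6% of KO and 40.9% of WT cells (background 0.651% and 1.81%). Chil3 stood at 2108 against 635 CPM, 3.32-fold higher (3.23 to 3.41), though in 29.3% against 34.6% of cells (background 0.570% and 1.17%), so no order was read from its shares. Cd300e and the scavenger receptor gene Cd36 were 3.48-fold and 2.98-fold higher. Of 5825 genes 24 were higher and 12 lower.

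The nonclassical and classical monocyte lists stood 0.29 and 0.22 higher in infected KO and macrophage differentiation at -0.22, and the classical median turned to -0.11 without doublet removal. The cytokine list stood at -0.12 with Tnf 1.49-fold higher, and MHC class I at 0.09. The other 9 lists, which included type I interferon-stimulated genes at 0.03 and IFN-gamma-induced effectors at 0.04, had medians from -0.03 to 0.09, and 6 of them changed sign under TMM, and chemokine and cell cycle genes with cells weighted equally. Within parts the chemokine median was -0.68 in classical and -0.60 in nonclassical monocyte-like cells and 0.26 in macrophage-like cells. Nonclassical monocyte-like cells made up 196 of 556 KO and 107 of 1101 WT cells of the class, and macrophage-like cells 210 and 514. Ctla2a, Cxcr6 and Ctla4 were 2.64-fold, 2.61-fold and 2.49-fold higher with all cells. Without the cells of both lineages they stood at 8.33, 1.28 and 3.20 CPM in KO and at 7.40, 2.09 and 2.85 in WT, and the Cxcr6 log2 ratio turned from 1.27 to -0.10. With HTO_6 cells alone 106 genes were at least 2-fold apart in place of 36, and with HTO_5 cells alone the log2 ratio of Cd300e turned from 1.54 to -0.16.

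**Figure D3:**
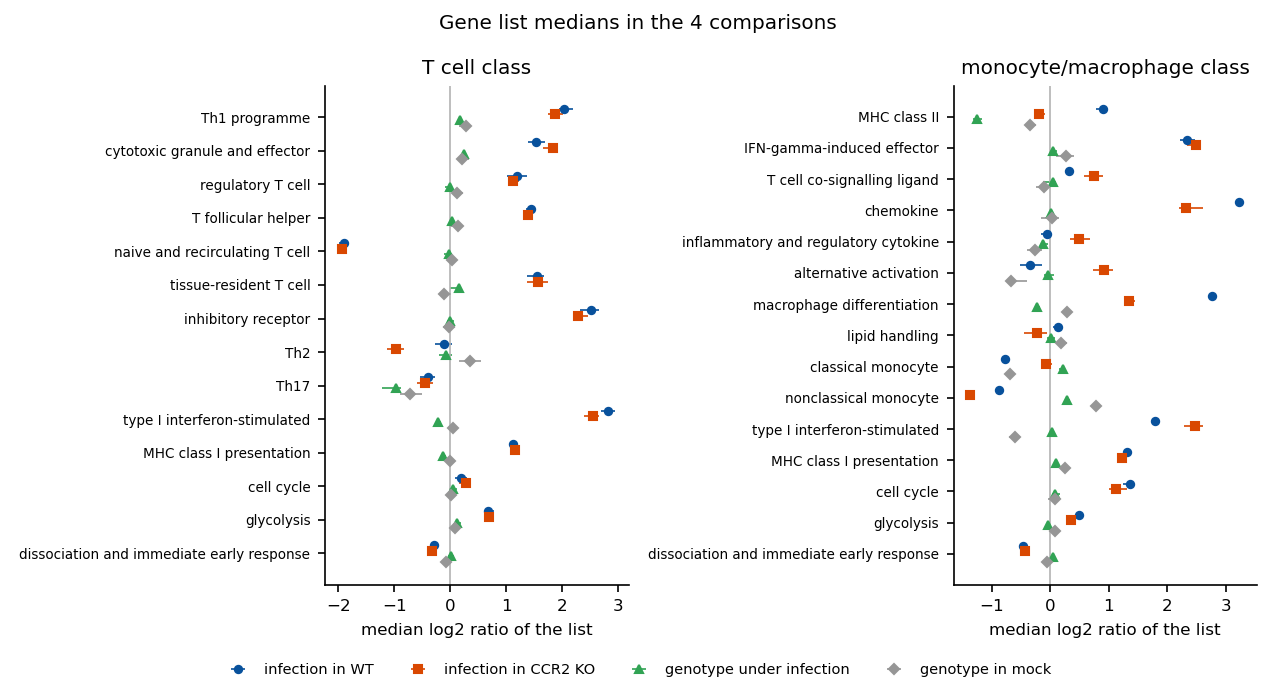
Points show the median log2 ratio of each gene list in the 4 comparisons, not centred on the median gene, with T cells and monocytes and macrophages in separate panels and lines for the interval from Poisson draws. The MHC class II list stood at 0.90 for infection in WT, -0.19 for infection in CCR2 KO and -1.24 for genotype under infection.

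In the mock libraries, KO and WT T cells were also close. Of 4600 genes 3 were at least 2-fold higher in KO and 4 lower. Ccl5 stood at 1087 against 538 CPM, 2.02-fold higher (1.92 to 2.13). The other genes, chosen after their values were seen, were Gzma (43.2 against 2.16 CPM, in 1.28% of KO T cells against a background of 0.299%) and the airway epithelial gene Scgb1a1 (350 against 44.2) as higher, and Ccr2, Il17a (18.5 against 58.7), Lyz2 and Ifitm3 as lower. Scgb1a1 and Lyz2 are genes of other cell types. The Th1 programme stood 0.27 higher and the cytotoxic list 0.22 higher, with Nkg7 at 168 against 111 CPM, Th2 0.34 higher over 3 members and Th17 at -0.71 over 4. The other 10 lists had medians from -0.11 to 0.14, and most of them changed sign in at least 1 setting, so no direction was read from them. With the mitochondrial limit of 5% the regulatory T cell median went from 0.12 to 0.74, the cytotoxic median to 0.51, Th2 to 0.94 and Th17 to -2.05, and the cell cycle median went from 0.005 to 0.45 with the T cells of cluster 9 joined. At that mitochondrial limit 66 genes were at least 2-fold apart in place of 7.

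Mock KO monocytes and macrophages had higher nonclassical and lower classical monocyte genes than mock WT. Cd300e stood at 295 against 80.9 CPM, 3.65-fold higher (3.30 to 4.05), and Scnn1a, the tetraspanin genes Cd9 and Cd81, Ly6a and the Fc receptor gene Fcgr4 were 3.92-fold, 3.26-fold, 3.12-fold, 3.89-fold and 2.90-fold higher. Besides Ccr2, Lyz1 was 7.06-fold lower (5.26 to 9.69), Fn1 2.86-fold (2.63 to 3.13), Ptgs2 2.88-fold, Slfn5 2.77-fold and Ifi203 2.46-fold lower. Of 5364 genes 62 were higher and 24 lower, and the median gene stood 0.07 higher. Relative to it, the nonclassical list stood 0.72 higher with 8 of 24 members higher (Pglyrp1 2.64-fold) and the classical list at -0.76 with 4 of 18 lower (Ms4a4c 2.07-fold). Alternative activation stood at -0.73 (Retnla 3.63-fold lower), type I interferon-stimulated genes at -0.67 with 3 of 20 members lower (Isg15 1.84-fold) and 1 higher, and MHC class II at -0.42 (H2-DMb1 1.63-fold lower). These class values hold different mixes of cells, and within classical and nonclassical monocyte-like cells the raw medians were 0.08 and -0.20 for MHC class II, -0.15 and -0.24 for type I interferon-stimulated genes, and 0.12 and -0.64 for alternative activation. The raw medians of the nonclassical list were 0.30 and -0.01 and of the classical list -0.19 and -0.32. Macrophage differentiation stood 0.22 higher (C1qc 2.79-fold, C1qa 2.53-fold), IFN-gamma-induced effectors 0.20, MHC class I 0.19 (H2-Q6 2.94-fold) and lipid handling 0.12 higher (Cd36 2.72-fold, while Fabp5 was 2.29-fold lower). Cytokines stood at -0.33, with Il1b 1.63-fold lower. The 5 remaining lists stood from -0.18 to 0.02, and the raw medians of chemokine, cell cycle and glycolysis genes changed sign under TMM. The raw chemokine median of 0.03 was -0.75 with the mitochondrial limit of 5% and 0.32 without the cells of both lineages. Classical monocyte-like cells made up 632 of 892 cells of the class in mock WT and 96 of 344 in mock KO, and nonclassical cells 225 in each. Treml4 was found in 23.2% of mock WT and 42.4% of mock KO cells (T cell background 0.141% and 0 of 1645), and Ly6c2 in 50.1% and 22.1% (T cell background 1.56% and 3.22%).

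The hashtags of the infected libraries carried different cells. HTO_5 marked 41.4% of the filtered barcodes of both infected libraries, HTO_6 marked 40.7% in WT and 41.1% in KO, and 17.6% and 17.1% were mixed. Classical monocyte-like cells made up 0.302% of HTO_5 and 29.3% of HTO_6 cells in WT, and 0.240% and 11.8% in KO. Nonclassical monocyte-like cells made up 0 of 1653 HTO_5 cells, which allows up to 0.181%, and 6.60% of HTO_6 cells in WT, and 0 of 1250 and 15.8% in KO. Macrophage-like cells made up 28.3% of HTO_5 and 2.28% of HTO_6 cells in WT, and 14.4% and 2.26% in KO. In HTO_6 T cells of WT, the hypoxia-induced gene Hilpda (277 against 20.7 CPM, 13.4-fold) and the early response genes Nr4a1 (11.1-fold), Fosl2 (7.50-fold) and Fos (6.63-fold) were higher, and Gzmk (2.92-fold), Ifit1bl1 (2.76-fold) and the transcriptional regulator gene Id2 (2.55-fold) were lower than in HTO_5 T cells. In KO, Hilpda was 12.3-fold, Fosb 10.5-fold and Nr4a1 10.0-fold higher in HTO_6 T cells, and Ifitm1 2.82-fold and Id2 2.44-fold lower. Relative to the median gene, at -0.10 in both, the dissociation list stood 1.26 higher in WT and 1.37 in KO T cells.

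In WT monocytes and macrophages, Ace (45.9-fold), Treml4 (59.1-fold), Nr4a1 (25.2-fold), Ifitm6 (24.7-fold) and Il1b (3150 against 239 CPM, 13.2-fold) were higher in HTO_6 cells, and Ccl8 (28.9-fold), Gpnmb (23.2-fold), Pf4 (44.0-fold), Arg1 (13.7-fold) and Cd63 (10.6-fold) were lower. In KO, Ace and Adgre4 were 80.8-fold and 137-fold higher, and Ccl8, Arg1, Mmp12, C3ar1 and Spp1 were 18.4-fold, 21.7-fold, 76.4-fold, 14.3-fold and 10.1-fold lower. Relative to the median gene, at -0.18 in WT and -0.17 in KO, the macrophage differentiation list stood at -1.77 in WT and -1.97 in KO, and the classical and nonclassical lists stood 1.90 and 2.06 higher in WT and 2.28 and 2.74 higher in KO. In HTO_5 monocytes and macrophages H2-Aa stood at 3180 CPM in WT and 1449 in KO, and in HTO_6 cells at 2850 and 994.5. These differences go with the different cell mixtures, since cluster 6 held 467 of 472 HTO_5 cells of the class in WT and clusters 3 and 7 held 107 and 429 of 619 HTO_6 cells.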

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

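Some of the tests below were chosen after the result had been seen. For the T and NK cell transcripts these were the tests of free RNA, of pairs with CD4 T cells and of Cd8a. The test of Gzmb in cells with no T lineage UMI was set before. For Ifitm1 the cluster test was chosen after.

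In monocytes and macrophages several results went in opposite directions with infection in WT and in CCR2 KO. The infection effect in KO minus that in WT was -1.09 for the MHC class II list, 1.27 for the alternative activation list, 1.98 for Ccr2, 2.44 for Chil3 and -1.09 for H2-Aa on the log2 scale. H2-Aa was the median member of the MHC class II list in both genotypes, so the list and H2-Aa give the same value. The median of the differences of its members was -0.96. None of these differences was tested, since each group was 1 library. The alternative activation medians were taken over 11 members in WT and 10 in KO, and over the same 11 members the KO median was 0.71 and the median difference 0.23. Within each hashtag this list had the same sign in WT and KO, at 0.42 and 0.54 with HTO_5 cells and at -0.47 and -0.36 with HTO_6 cells, so its opposite direction was lost there. The MHC class II medians were both positive with the mitochondrial limit of 5%, 0.63 in WT and 0.23 in KO. Within parts they went opposite ways, at 0.89 in WT and -0.56 in KO for classical and at 1.40 and -0.39 for nonclassical monocyte-like cells. With HTO_5 cells alone the Chil3 ratio in KO was -0.79, below 0 as in WT. Part of the hashtag counts matched neither tag sequence, 5.73% in infected WT and 6.59% in infected KO, and these counts were not used here.

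T and NK cell transcripts such as Gzma and Gzmb appeared in monocytes and macrophages of the infected libraries. Free RNA is argued against, since macrophage-like cells held 80.9 times (61.2 to 109) the T lineage UMIs per cell of nonclassical monocyte-like cells in infected WT and 75.0 times (62.9 to 90.1) in infected KO. Cluster 21, with leading genes of cytotoxic cells and nonclassical monocytes, lay outside the nonclassical part. It held 6 cells of infected WT and 21 of infected KO, and leaving them out may have raised both ratios. Pairs with cells of the CD4 T cell class alone are argued against by Gzma per T lineage UMI in cells of both lineages at 19.0 times (18.1 to 19.9) that of the class, and expression by the myeloid cells themselves by Gzmb in cells with no T lineage UMI at 1.62% (1.19 to 2.16) of its class level. Cd8a per T lineage UMI in cells of both lineages stood at 149 times (83.7 to 292) that of the CD4 T cell class. That goes with droplets that hold a cytotoxic lymphocyte from outside that class. Outside any test, Cd4 stood at 78.7 CPM in cells of both lineages in infected WT and 136 in infected KO. It stood at 13.4 and 5.05 CPM in cluster 12, so pairs with CD4 T cells may be among them. The NK cell gene Ncr1 stood at 0.916 and 0 CPM in cells of both lineages and at 466 and 441 in NK cells. The sort was for monocytes and CD4 T cells, yet cluster 12, with Prf1 and Cd8a among its leading genes, held 49 cells of infected WT and 150 of infected KO, and NK cells numbered 14 and 28. Chance doublets, bound cell pairs and engulfed lymphocytes were not separated.

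MHC class II genes were lower in monocytes and macrophages of infected KO than of infected WT. Another mix of monocyte and macrophage parts is argued against by a median of -1.11 (-1.15 to -1.07) in the least different part, and another mix of hashtags by -1.13 (-1.16 to -1.07) in the less different hashtag. Without cells that held a B cell or dendritic cell marker the median was -1.07 (-1.16 to -0.99). A difference between the genotypes and a difference between 2 single libraries cannot be told apart.

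Ifitm1 was higher in T cells of infected KO than of infected WT. Free RNA is argued against by Ifitm1 UMIs per cell that were 492 times (136 to 4062) higher in the highest than in the lowest T cell cluster of infected KO. Another mix of clusters is argued against by a ratio of 2.48 (2.28 to 2.71) in the lowest of the 3 clusters compared, 1, 5 and 8, which held 98.3% of the T cell class's Ifitm1 UMIs in infected WT and 99.1% in infected KO, and another mix of hashtags by 2.26 (2.10 to 2.43) in the lower hashtag. Whether the genotype or the single library carries the difference stays open.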

How the results depend on the processing

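No paired analysis was possible because each group was 1 library. Leaving out the cells of both lineages and joining the cycling cells to the T cell class were added after the data had been seen, as were the comparisons within monocyte and macrophage parts. For the values below the cause of the move was not tested. A mitochondrial limit of 5% moved the most shares. T cells then made up 13.4% of mock WT, 39.0% of mock KO, 49.8% of infected WT and 47.7% of infected KO, and monocytes and macrophages 75.9%, 42.5% and 27.6% of the first 3. Ccr2 stood at 73.0, 12.1, 517 and 142 CPM in T cells of the 4 libraries and at 679 and 353 CPM in monocytes and macrophages of mock and infected WT. The log2 ratio of Egr1 for infection in KO monocytes and macrophages turned from -1.44 to 0.10, and the mock genotype count in T cells rose from 7 to 66. With at least 1000 genes per cell that count was 13, with a minimum level of 50 CPM it was 4 and with a pseudocount of 1 it was 11. Without doublet removal the genotype count under infection in monocytes and macrophages rose from 36 to 63, and their share of infected KO was 24.7%. At clustering resolution 1.5 T cells made up 38.0%, 69.5% and 50.4% of mock WT, mock KO and infected WT, and Ccr2 in mock WT T cells was 23.5 CPM. A pseudocount of 1 gave genotype counts under infection of 19 in T cells and 74 in monocytes and macrophages, and 166 in place of 86 in mock monocytes and macrophages. The mean over cells gave 69 in place of 36.

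Hashtag purity of 90% left 67.3% of infected WT and 39.4% of infected KO barcodes mixed, and 65% left 3.36% and 6.79%. At 90% T cells made up 46.9% of infected WT and 46.9% of infected KO, monocytes and macrophages 39.9% and 25.8%, and Ccr2 in infected WT was 449.5 CPM in T cells and 390.1 in monocytes and macrophages. The genotype count under infection in T cells rose from 10 to 16. With HTO_5 cells only it was 17, and the infection counts in monocytes and macrophages were 1356 in WT and 1491 in KO in place of 646 and 797. T cells made up 58.3% and 62.6% of infected WT and KO and monocytes and macrophages 28.6% and 14.6%, and Ccr2 was 541 and 158 CPM in T cells and 278 in WT monocytes and macrophages. The log2 ratios of Chil3 and Ly6c2 for infection in KO turned from 1.66 to -0.79 and from 1.24 to -0.022, and that of Cd300e for genotype under infection from 1.54 to -0.16. With HTO_6 cells only the infection counts were 276 and 395 and the genotype count under infection in monocytes and macrophages 106. T cells made up 49.9% and 39.4%, monocytes and macrophages 38.2% and 29.8%, and Ccr2 was 357 and 72.4 CPM in T cells and 548 in WT monocytes and macrophages. Trem2 for infection in WT turned from 1.02 to -0.20 and C1qa for infection in KO from 1.33 to -0.45. Without cells of both lineages T cells made up 58.3% and 56.5% and monocytes and macrophages 30.3% and 19.8% of infected WT and KO, Ccr2 in monocytes and macrophages was 454 and 59.6 CPM, the cell cycle list for infection in KO monocytes and macrophages turned from 1.12 to -0.039 and Cxcr6 for genotype under infection from 1.27 to -0.10. With cycling cells joined, T cells made up 77.8% of mock KO, 60.9% of infected WT and 59.5% of infected KO, Ccr2 in T cells was 412 and 115 CPM in infected WT and KO, and the cell cycle median of T cells rose to 1.15 and 0.85 for infection in WT and KO and to 0.22 for genotype under infection.

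Under TMM the higher and lower genes were 454 and 281 in T cells and 409 and 215 in monocytes and macrophages for infection in WT, 442 and 321 in T cells for infection in KO, and 38 and 36 for mock genotype in monocytes and macrophages. Of 32 list medians at least 1 log2 from 0, 29 stayed so under TMM, 28 with the mean over cells, 27 with the 5% limit, 26 with HTO_6 cells only and 32 at both other resolutions. All 32 kept their sign in each setting apart from 1 without cells of both lineages. Of 257 named gene ratios at least 1 log2 from 0, 242 stayed so under TMM, 239 with the mean over cells, 225 with HTO_6 cells only and 249 with HTO_5 cells only. Of 104 shares of cells with a UMI, 71 moved with thinning to 1000 UMIs and 80 without thinning. Some list medians of the report also turned under single settings. With HTO_6 cells only they were 0.24 for Th17 and 0.25 for cytokines for infection in WT, -0.12 for lipid handling for infection in WT, 0.022 for dissociation genes for infection in KO monocytes and macrophages, and -0.34 for chemokines for genotype under infection. With HTO_5 cells only they were 0.12 for lipid handling for infection in KO and 0.21 for cytokines for genotype under infection, and with hashtag purity of 90% the tissue-resident list for genotype under infection was -0.078. With the 5% limit the cell cycle list for infection in WT T cells was -0.17, and the tissue-resident and type I interferon-stimulated lists for mock genotype in T cells were 0.28 and -0.19.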

Other observations

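Comparisons within the parts of the monocyte/macrophage class were added after the data had been seen, and the filter aimed at free RNA was not applied to them. In classical monocyte-like cells of the infected libraries, Chil3 stood at 6297 CPM in KO and 1142 in WT, together with the neutrophil genes S100a8 (363 and 39.1) and Lcn2 (127 and 10.7) and the T cell genes Cd3d (193 and 44.9) and Icos (123 and 26.9). S100a8 failed the filter aimed at free RNA in the whole class, neutrophils numbered 88 in infected KO and 6 in infected WT, and cells of both lineages made up 18.0% and 9.58% of this part. In the same cells the complement genes C1qc, C1qb and C1qa stood at 61.1 and 278, 157 and 655, and 167 and 530 CPM. MHC class II genes stood at -1.16 in KO over WT. In nonclassical monocyte-like cells of the infected libraries, Ly6a stood at 1839 CPM in KO and 639.5 in WT, and Ccnd2 at 526 and 143, while S100a4 stood at 74.8 and 603.5, H2-Eb1 at 151 and 1151, and Cxcl10 at 49.5 and 312. The MHC class II list stood at -2.08 and the type I interferon-stimulated list at 0.84 with 10 of 25 members higher. In macrophage-like cells Inhba stood at 211 CPM in KO and 65.3 in WT, together with Cxcl2 (287 and 55.9) and S100a8 (217 and 92.2), which failed that filter, while H2-Eb1 stood at 1217 and 2928 and Cxcl9 at 147 and 359, with the MHC class II list at -1.11.

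Some cell types outside the 2 classes also had different shares in infected KO. Neutrophils made up 0.289% of mock WT, 0.404% of mock KO, 0.182% of infected WT and 3.51% (2.83 to 4.31) of infected KO, where 80 of 88 carried HTO_5. Mature migratory dendritic cells made up 0.404%, 0.494%, 0.486% and 3.04% (2.40 to 3.78). NK cells made up 0.231%, 0.854%, 0.426% and 1.12%. The cells were sorted for monocytes and CD4 T cells, so these shares describe what passed the sort.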
